A study of Homo sapiens with 18 samples.

How the data were processed

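Gene expression was measured on Illumina HumanHT-12 version 3 BeadChips in 3 human prostate cancer cell lines, LNCaP, VCaP and DU145. Per the labels' design text, cells were transduced with an adenovirus carrying GLIPR1 or with a control adenovirus carrying lacZ, kept in complete medium for 24 h, starved of serum for 24 h and given serum again for 30 min before RNA was taken. Each line had 3 arrays per virus, which made 6 groups and 18 arrays. Groups and replicate numbers came from the sample titles. The title of VCaP GLIPR1 array 2 lacks the first letter of the line, and its source name gives VCaP. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, RNA was isolated with a mirVana kit, and 500 ng of total RNA was amplified into biotin-labelled cRNA. Per the submitters' processing notes, values were exported with BeadStudio; its version and the background step were not given in the sources used here.

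Both deposited tables listed 48803 probes, and every column was matched to a sample. For the LNCaP and VCaP arrays the authors deposited linear signal intensity per probe, without detection p-values. Array medians lay between 92.0 and 101 intensity units and lowest values between 50.5 and 60.9, so no background had been subtracted, and the quartiles differed between arrays. For the DU145 arrays the same table held log2 values with equal quantiles on the 6 arrays, and 100% of them equalled the second deposited table. That table held log2 values for all 18 arrays. Its 12 LNCaP and VCaP columns had equal quantiles and a median of 6.585, and the 6 DU145 columns were equalized as another set with a median of 6.205. Its LNCaP and VCaP columns followed the log2 of the deposited intensities with a correlation of at least 0.998 on each array, which gives scale and direction; what the authors did to the background stays unknown. The number of arrays limits the precision of every value.

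The DU145 values did not follow the probe identifiers beside them. The rank correlation between a DU145 array and an LNCaP or VCaP array over all probes lay between -0.0316 and -0.0191. It was 0.752 to 0.783 between LNCaP and VCaP arrays and 0.908 to 0.919 among DU145 arrays. No gene was therefore named from the DU145 columns. They were tested as table entries in a fit of their own, and their genes were not analysed here. The design written before the data were examined called for 1 fit over 18 arrays. It could not be used, because the DU145 values did not follow the probe identifiers and were given only as log2 values equalized as a set of their own. LNCaP and VCaP were fitted together over 12 arrays, with 4 group means and 8 residual degrees of freedom, and the mean effect and the difference between lines cover these 2 lines.

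LNCaP and VCaP intensities were corrected with normexp (offset 50) and quantile normalized in limma 3.58.1 under R 4.3.3. Probes at or above the array median on at least 3 arrays were kept, which left 30557 probes. DU145 values were used as deposited under the same filter, which left 24745 entries and a fit with 4 residual degrees of freedom. Group differences were tested on the log2 scale with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment over the tested probes of each contrast and a threshold of 0.05. The contrasts were GLIPR1 minus lacZ in each line, the mean of the LNCaP and VCaP effects, the VCaP effect minus the LNCaP effect, and VCaP lacZ minus LNCaP lacZ. Of all probes, 28098 had 1 gene symbol in the platform annotation, 13 had several and 20692 had none; no gene was named from the last 2 kinds. Checking symbols by Entrez identifier against RefSeq names of GRCh38.p14 changed 0 of them. The tested probes covered 15111 genes, and each gene was represented by its brightest tested probe. No genome coordinates were used.

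The genes named in the text came from a fixed rule. In each line these were GLIPR1, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, and MYC, CTNNB1, AURKA, TPX2, HSPA8, CCND1 and CDKN1A. Up to 4 members of each fixed gene list with the largest moderated statistic were added. For the mean effect the rule took the 10 largest rises and falls with the same sign in both lines, and for the difference the 10 genes with the largest statistic. Unnamed probes and placeholder symbols were skipped. Not every gene that the rule selected is printed, and most genes whose call was lost without any of several single arrays were left out of the text.

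There were 25 fixed gene lists, tested and adjusted together; 1 of them is counted among these and its result is not reported here. The others covered mitosis and spindle, DNA replication, MYC targets, p53 targets, apoptosis regulators, the unfolded protein response with ATF4 targets, heat shock chaperones, oxidative stress with NRF2 targets, androgen response, interferon response, NF-kB with inflammatory cytokines, WNT and beta-catenin targets, TGF-beta with SMAD and matrix genes, cholesterol synthesis, glycolysis with hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, replication-dependent histones and immediate early genes. Further lists held luminal markers of LNCaP and VCaP, and markers of fibroblasts, leukocytes and the embryonic kidney cells in which adenovirus is packaged. The list called GLIPR1 study genes was taken from knowledge of the study itself, so its direction is not independent evidence, and it shares members with the mitosis list. Lists were tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation, and with fry. With the estimated correlation 6 of 9 called lists in LNCaP, 3 of 7 in VCaP, 3 of 11 for the mean effect, 5 of 11 for the difference and 0 of 10 between the lacZ arrays stayed past the threshold.

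Samples with the same number were compared by the correlation of their deviations from the group means. In LNCaP these were 0.66, 0.47 and 0.32 for replicates 1, 2 and 3, so the numbers pair replicate 1 there. Replicate 1 stood apart under both viruses, which by itself raises the values among replicates 2 and 3. Between replicates 2 and 3 of different viruses they were 0.22 and 0.18, so the pairing of these replicates is less clear. The pairing comes from the data and is not stated in the labels. A fit with the replicate number as a block within each line was an alternative. All pairs of arrays were compared before averaging, and 0 pairs held identical values. VCaP GLIPR1 arrays 1 and 2 correlated at 0.995, as VCaP lacZ pairs did at 0.994 to 0.995. Each array was counted as a sample, although these correlations cannot show that the arrays came from separate preparations.

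The fits were tested on simulated data with the real probe means and 200 changed probes. Simulated samples were independent, with a single real spread per probe in all groups of a fit. The simulation left out the wider spread of the VCaP GLIPR1 arrays and the pairing in LNCaP. The shares may therefore differ from those in the real data, also for the block. At a 2-fold change the fit recovered 80.6% of the changed probes in LNCaP, 88.1% in VCaP, 95.5% for the mean effect, 31.3% for the difference between lines and 82.1% in DU145. At a 1.5-fold change these shares were 20.9%, 28.4%, 50.7%, 1.49% and 37.3%. With the block, the LNCaP fit recovered 73.1% at 2-fold. Alternatives were no background correction, a shift of each array to a common 75th percentile, the second deposited table, other filters on dim probes, an intensity trend with a robust prior, arrayWeights, the block, each line alone, stricter thresholds and leaving out each array in turn. The 75th percentile shift moved the median change of all probes to -0.118 in VCaP and -0.134 for the difference between lines; changes under that setting stand relative to these medians. Alternatives added after seeing the data left out VCaP GLIPR1 arrays 1 and 2 together, filtered at the 75th percentile, or used a score of each array on the contrast between LNCaP replicate 1 and replicates 2 and 3 as a covariate. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.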

Results

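Transcript levels were measured on 18 arrays from 3 prostate cancer cell lines, each transduced with adenovirus carrying GLIPR1 or the control lacZ. All 3 lines were established from prostate cancer metastases, and LNCaP and VCaP respond to androgen. GLIPR1 encodes a secreted protein of the cysteine-rich CAP family, and lacZ encodes bacterial beta-galactosidase. Each of the 6 groups held 3 arrays. Array medians of the deposited intensities lay between 92.0 and 101 units in LNCaP and VCaP, and the DU145 arrays were deposited on the log2 scale with a median of 6.205. LNCaP and VCaP were compared by gene over 30557 probes and 15111 genes. The DU145 values did not follow their probe identifiers and were compared without gene names.

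The probe for GLIPR1 itself did not show a transgene on the arrays labelled GLIPR1. In LNCaP its log2 level was 6.10 ± 0.06 with lacZ and 6.18 ± 0.16 with GLIPR1 (SD, n = 3 each), a change of 0.08 (SE 0.14, limma adjusted p = 0.955, two-sided exact permutation p = 0.5). In VCaP it was 6.82 ± 0.21 with lacZ and 6.09 ± 0.18 with GLIPR1, a change of -0.74 (SE 0.14, limma adjusted p = 0.00500, exact permutation p = 0.1). With 3 arrays against 3 the exact test cannot go below 0.1. Without VCaP GLIPR1 arrays 1 and 2 the VCaP change was -0.56 with adjusted p = 0.166. The array median was 6.34, so the probe read below it on every LNCaP array and on the VCaP arrays labelled GLIPR1. Where this probe lies in the transcript, and whether the adenoviral construct contains that part, is not given in the sources used here. The direction of every comparison therefore rests on the labels.

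**Figure D1:**
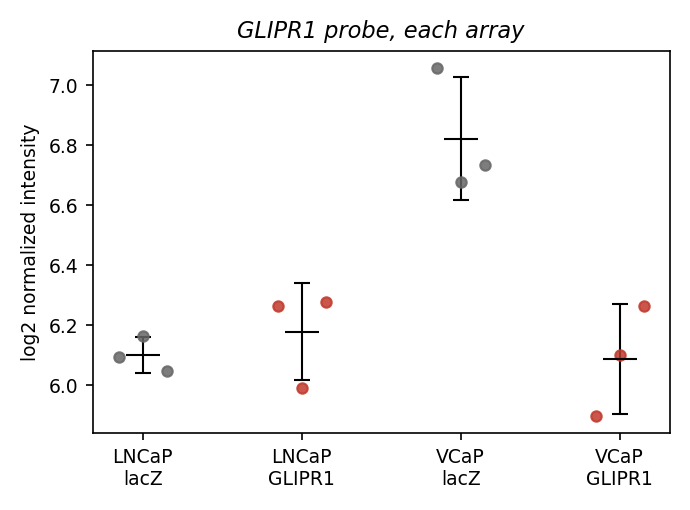
Log2 normalized intensity of the GLIPR1 probe on each LNCaP and VCaP array, with group means and SD as bars (n = 3). The LNCaP groups overlap, and the VCaP arrays labelled GLIPR1 read at most 6.26 against at least 6.68 with lacZ.

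The arrays separated first by cell line and then within VCaP. Component 1 held 75% of the variance and parted LNCaP from VCaP, and component 2 held 13.2%. On component 2, VCaP GLIPR1 arrays 1 and 2 lay at 61.2 and 61.3, and array 3 lay at -15.2, closer to the VCaP lacZ arrays at -24.6 to -31.8. Both LNCaP arrays numbered 1 also lay high, at 18 and 20.7. Arrays 1 and 2 of the VCaP GLIPR1 group correlated at 0.995 with each other and at 0.962 with array 3. VCaP results are therefore also given without arrays 1 and 2. That fit leaves 1 VCaP GLIPR1 array, which is assumed to vary like the other groups. The p-values and counts of that fit are therefore no stronger evidence than those with all arrays.

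**Figure D2:**
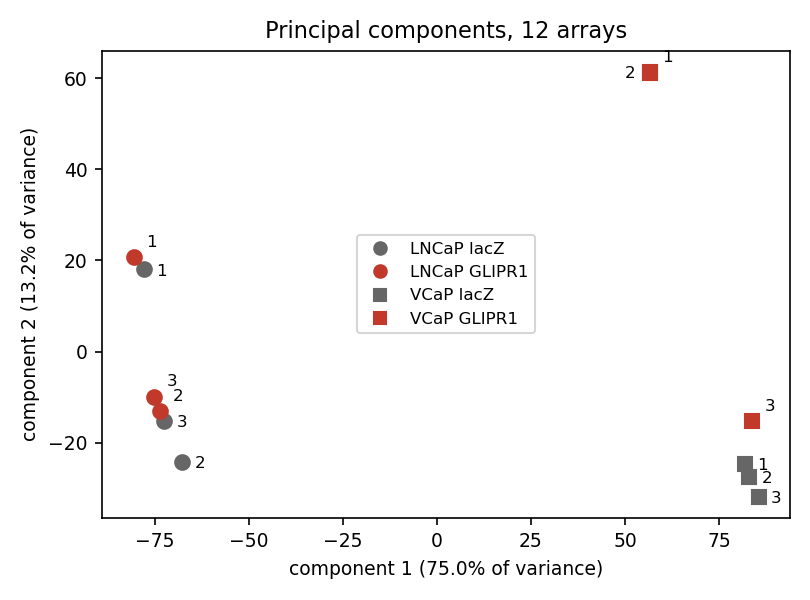
Scores of the 12 LNCaP and VCaP arrays on principal components 1 and 2 of the normalized log2 values, which hold 75% and 13.2% of the variance; numbers beside the points are replicate numbers. VCaP GLIPR1 arrays 1 and 2 lie near 61 on component 2, and array 3 at -15.2.

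In LNCaP, genes of mitosis and the spindle fell together in the arrays labelled GLIPR1. Of 50 members, 39 fell and 0 rose, and 48 fell when adjusted over the list alone; the median change was -1.10 (camera adjusted p = 6.17e-71, and adjusted p = 0.00576 with an estimated correlation). KIF20A, a kinesin needed for cytokinesis, fell by 1.71 (SE 0.13, limma adjusted p = 7.79e-05), and PRC1, which bundles the microtubules of the central spindle, fell by 1.59 (SE 0.15, adjusted p = 0.000210). CCNB2 and CCNA2, the mitotic cyclins B2 and A2, fell by 1.66 and 1.34. BIRC5, which encodes survivin, fell by 1.64 (SE 0.23, adjusted p = 0.00290), and CDC20, an activator of the anaphase-promoting complex, fell by 1.63 (SE 0.23, adjusted p = 0.00376). AURKA, the mitotic kinase Aurora A, fell by 1.38 and its activator TPX2 fell by 1.31. TOP2A and NUSAP1 changed by -1.57 and -1.56. UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, changed by -1.75 (adjusted p = 0.00766), and without LNCaP GLIPR1 array 2 by -1.59 (adjusted p = 0.0514). Against the mean of the lacZ arrays the list's median was -1.20, -1.17 and -1.01 on LNCaP GLIPR1 arrays 1, 2 and 3.

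**Figure D3:**
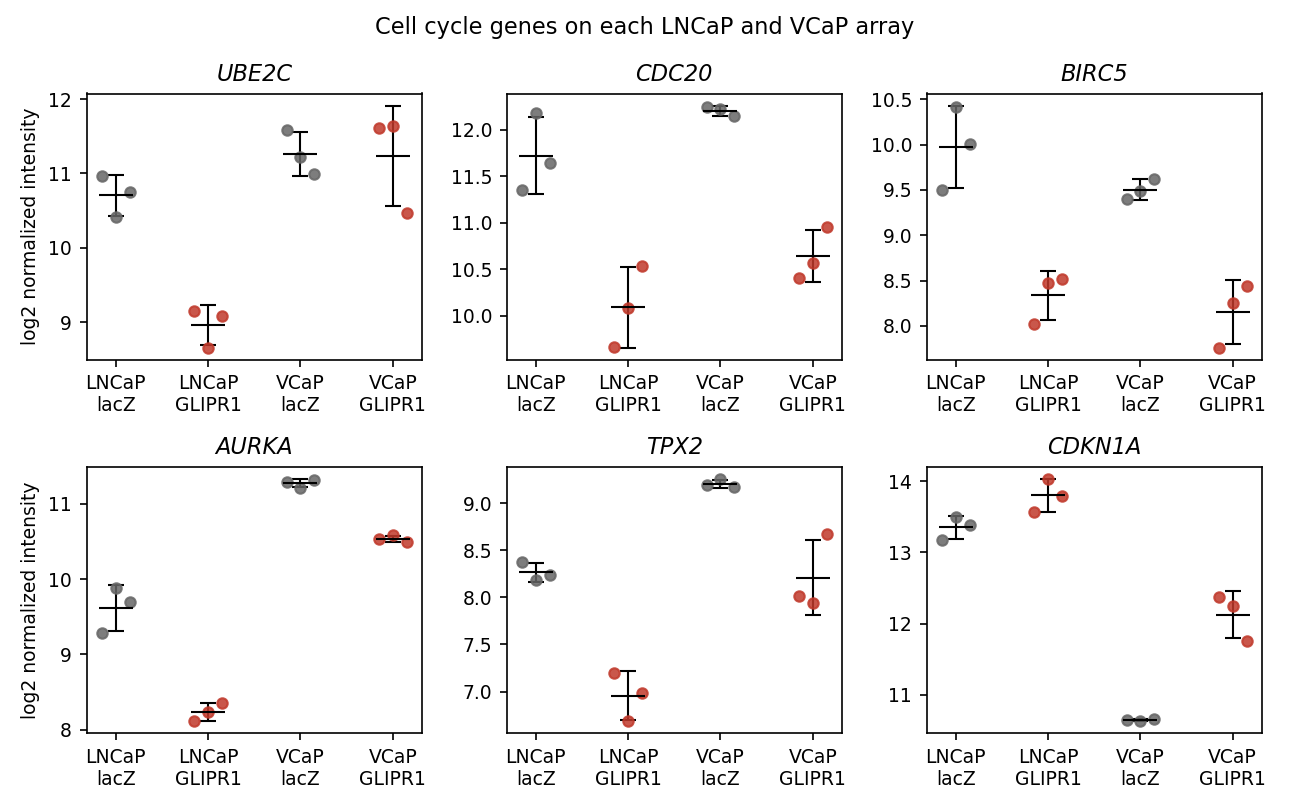
Log2 normalized intensity of UBE2C, CDC20, BIRC5, AURKA, TPX2 and CDKN1A on each LNCaP and VCaP array, with group means and SD as bars (n = 3). The LNCaP arrays labelled GLIPR1 lie below the lacZ arrays for UBE2C, CDC20, BIRC5, AURKA and TPX2, and in VCaP the UBE2C groups overlap.

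Androgen-regulated and luminal genes were also lower in LNCaP. Of the 37 androgen response genes 5 fell and 0 rose, 7 when adjusted over the list alone, with a median of -0.27 (camera adjusted p = 6.21e-07, and adjusted p = 0.00576 with an estimated correlation). Of the 12 luminal markers 4 fell and 0 rose, 8 when adjusted over the list alone, with a median of -0.51 (adjusted p = 5.85e-08, and adjusted p = 0.00777 with an estimated correlation). TMPRSS2, an androgen-induced serine protease, fell by 1.06 (SE 0.13, adjusted p = 0.000918). KLK2, a kallikrein of the prostate, changed by -1.0 (SE 0.17, adjusted p = 0.010), by -0.91 without LNCaP lacZ array 2 (adjusted p = 0.0579), and fitted on the 6 LNCaP arrays alone its adjusted p was 0.0554. PMEPA1 changed by -0.71 (adjusted p = 0.010), and without LNCaP lacZ array 2 by -0.62 (adjusted p = 0.0531). Both lists share these 3 genes.

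Several single genes rose strongly in LNCaP. NTS, which encodes the peptide neurotensin, rose by 2.41 (SE 0.22, adjusted p = 0.000210). LUM, which encodes the matrix proteoglycan lumican, rose by 2.27 (SE 0.16, adjusted p = 2.60e-05), and CBLN2, which encodes the synaptic protein cerebellin 2, rose by 2.0 (SE 0.11, adjusted p = 5.14e-06). FHL2, a LIM-domain transcriptional cofactor, rose by 1.77, and MECOM, a zinc-finger transcription factor, by 1.54. NECTIN3, a cell adhesion molecule, rose by 1.47. MYB, a transcription factor of proliferating progenitors, changed by 1.28 (adjusted p = 0.00877), and by 1.23 without LNCaP GLIPR1 array 2 (adjusted p = 0.0550). CT45A3 changed by 1.62, and its gene is uncertain because the family holds near-identical copies. Of the 33 TGF-beta, SMAD and matrix genes 3 rose and 1 fell, 5 and 2 when adjusted over the list alone, and the list did not pass (median 0.05, adjusted p = 0.115). Its members CCN2, a matricellular protein, VIM, the intermediate filament vimentin, and SNAI2, a transcription factor of mesenchymal cells, rose by 0.98, 1.06 and 0.70.

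Further lists passed the camera test in LNCaP with few called members. Of the 49 DNA replication genes 0 fell, 5 when adjusted over the list alone and 4 with the replicate block, at a median of -0.23 (adjusted p = 8.81e-06, and adjusted p = 0.110 with an estimated correlation). CDC45, part of the replicative helicase, stood at -0.99 (adjusted p = 0.0718); with the replicate block its adjusted p was 0.00186, and without LNCaP lacZ array 1 it stood at -1.29 (adjusted p = 0.00873). The 32 p53 targets lay higher at a median of 0.20 (adjusted p = 0.00105, and adjusted p = 0.0152 with an estimated correlation), with 0 called, 3 when adjusted over the list alone and 2 with the replicate block. These were TP53I3 at 0.52 (adjusted p = 0.0591, and 0.0334 with the block) and TIGAR at 0.68 (adjusted p = 0.0601, and 0.0392 with the block). Of the 40 immediate early genes 3 rose and 0 fell, 6 when adjusted over the list alone, at a median of 0.07 (adjusted p = 0.00550, and adjusted p = 0.110 with an estimated correlation). DUSP5, a phosphatase that inactivates ERK, and CCN2 were among them, at 0.96 and 0.98. The immediate early list did not pass without LNCaP GLIPR1 array 1 (0.02, adjusted p = 0.0507) or without LNCaP lacZ array 2 (0.01, adjusted p = 0.154). Of the 37 glycolysis and hypoxia genes 1 fell, 3 when adjusted over the list alone, at a median of -0.16 (adjusted p = 0.00484, and adjusted p = 0.0239 with an estimated correlation). Of the 11 fibroblast markers 1 rose, LUM, and 2 when adjusted over the list alone, at a median of 0.09 (adjusted p = 0.0172, and adjusted p = 0.0743 with an estimated correlation; with no filter on dim probes the median was 0.07 and adjusted p = 0.0616). Of the 12 GLIPR1 study genes 4 fell, among them AURKA, TPX2 and BIRC5 of the mitosis list, and 5 fell and 1 rose when adjusted over the list alone. Their median was -0.27 (adjusted p = 0.000158, and adjusted p = 0.0146 with an estimated correlation); this list came from knowledge of the study and is not independent evidence.

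The remaining lists reported here did not pass in LNCaP. Medians and adjusted p were 0.04 and 0.881 for MYC targets, -0.04 and 0.857 for apoptosis regulators, -0.12 and 0.124 for the unfolded protein response, 0.06 and 0.349 for heat shock chaperones and -0.02 and 0.796 for NRF2 targets. They were 0.0094 and 0.527 for interferon response, 0.0040 and 0.633 for NF-kB, 0.0027 and 0.583 for WNT targets, -0.11 and 0.152 for cholesterol synthesis, 0.05 and 0.257 for oxidative phosphorylation and 0.04 and 0.349 for ribosomal proteins. They were 0.02 and 0.128 for histones, -0.0031 and 0.325 for leukocyte markers and -0.05 and 0.857 for embryonic kidney markers. For WNT targets and leukocyte markers the median and the direction of the test differed in sign, and for NRF2 targets the mean was 0.05 and the median and test were negative. MYC targets, apoptosis regulators, the unfolded protein response and WNT targets held 1 lower member each, heat shock chaperones, interferon response, NF-kB and ribosomal proteins 1 higher member each, NRF2 targets 1 of each and the others 0. Oxidative phosphorylation passed without LNCaP lacZ array 3 (0.12, adjusted p = 0.0176), as did cholesterol synthesis (-0.12, adjusted p = 0.0467). Histones passed without LNCaP GLIPR1 array 2 (0.06, adjusted p = 0.0404) or lacZ array 1 (0.12, adjusted p = 0.0448), and the unfolded protein response without LNCaP GLIPR1 array 2 (-0.16, adjusted p = 0.0324). The replicate block raised the called members from 1 to 5 for interferon response and from 1 to 3 for the unfolded protein response. With it histones held 2 higher and 1 lower member, NRF2 targets 3 higher and 1 lower, and NF-kB 2 higher. GBP1, an interferon-induced GTPase, rose by 1.01 (SE 0.14, adjusted p = 0.00248). SLC7A5, an amino acid transporter, changed by -0.64 (adjusted p = 0.00908), and by -0.61 without LNCaP GLIPR1 array 3 (adjusted p = 0.0525). MYC stood at -0.34 (adjusted p = 0.362), CCND1 at -0.42 (adjusted p = 0.480), CDKN1A at 0.45 (adjusted p = 0.313), HSPA8 at -0.20 (adjusted p = 0.708) and CTNNB1 at 0.02 (adjusted p = 0.999). The sign of CTNNB1 turned without LNCaP GLIPR1 array 1 (-0.37), lacZ array 2 (-0.13) or lacZ array 3 (-0.26) and under the 75th percentile shift (-0.01).

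In all, 394 of 30557 probes passed the threshold in LNCaP, 201 higher and 193 lower, and 115 of them differed by at least 2-fold. They held 139 genes with a higher and 159 with a lower probe. With the replicate block 671 probes passed. The count was 248, 182 and 210 without LNCaP GLIPR1 array 1, 2 or 3, 223 and 239 without lacZ array 2 or 3, 947 without VCaP GLIPR1 array 3 and 721 without VCaP GLIPR1 arrays 1 and 2, which enter through the shared estimate of the spread.

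In VCaP, mitosis and spindle genes were lower as well. Of 50 members 41 fell and 0 rose, 42 when adjusted over the list alone, at a median of -0.98 (adjusted p = 1.41e-20, and adjusted p = 0.0808 with an estimated correlation). Against the lacZ mean the median was -1.10 on both arrays 1 and 2 and -0.62 on array 3, the only GLIPR1 array left without arrays 1 and 2. KIF14 and KIF20A, both kinesins of cytokinesis, fell by 1.42 and 1.06, and CDC25C, the phosphatase that activates CDK1, fell by 1.27. The values of these genes without arrays 1 and 2 were -1.09, -0.86 and -1.13. BIRC5 changed by -1.35 (SE 0.23, adjusted p = 0.00283), AURKA by -0.74 (SE 0.14, adjusted p = 0.00556) and TPX2 by -1.0 (SE 0.18, adjusted p = 0.00427). Without arrays 1 and 2 these were -1.06 (adjusted p = 0.0883), -0.77 (adjusted p = 0.0836) and -0.54 (adjusted p = 0.197).

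The genes MYC, CCND1 and CDKN1A changed in VCaP. MYC, a transcription factor that drives growth, fell by 1.16 (SE 0.13, adjusted p = 0.000366), and stood at -1.13 without arrays 1 and 2. CCND1, cyclin D1, changed by -0.97 (SE 0.19, adjusted p = 0.00667) and by -1.31 without them. CDKN1A, which encodes the CDK inhibitor p21, rose by 1.48 (SE 0.17, adjusted p = 0.000324), and by 1.11 without them. Of the 45 MYC targets 15 fell and 0 rose, 19 and 1 when adjusted over the list alone, at a median of -0.29 (adjusted p = 0.00349, and adjusted p = 0.0328 with an estimated correlation). POLR1B, a subunit of RNA polymerase I, fell by 0.99, and stood at -0.92 without arrays 1 and 2. Without arrays 1 and 2 the MYC target median was -0.30, and without VCaP GLIPR1 array 3 it was -0.27 (adjusted p = 0.0710). Of the 29 WNT targets 8 fell and 0 rose, 11 and 5 when adjusted over the list alone, and the list did not pass (median -0.08, adjusted p = 0.160). LEF1, a transcription factor of WNT signalling, fell by 1.52 (SE 0.12, adjusted p = 5.18e-05), and stood at -1.42 without arrays 1 and 2. CTNNB1, which encodes beta-catenin, stood at 1.41 (SE 0.47, adjusted p = 0.0675), at 0.33 without arrays 1 and 2 (adjusted p = 0.883) and at 1.95 without array 3 (adjusted p = 0.00130).

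Sterol synthesis and stress genes rose in VCaP. Of the 30 cholesterol synthesis genes 11 rose and 0 fell, 15 and 1 when adjusted over the list alone, at a median of 0.61 (adjusted p = 1.59e-06, and adjusted p = 0.00807 with an estimated correlation). HMGCS1, the cytosolic HMG-CoA synthase, rose by 1.17 (SE 0.23, adjusted p = 0.00674), and INSIG1, a feedback regulator of the pathway, by 0.93; without arrays 1 and 2 they were 1.68 and 1.15. Without those arrays the list's median was 0.44. Of the 31 heat shock chaperones 10 rose and 2 fell, 11 and 2 when adjusted over the list alone, at a median of 0.24 (adjusted p = 0.000793, and adjusted p = 0.0324 with an estimated correlation). HSPB1, the small heat shock protein HSP27, rose by 1.30 and was 1.73 without arrays 1 and 2; HSPA1A rose by 1.40 (1.31 without them), and its probe cannot be assigned to it alone because a near-identical copy exists. Without both arrays the chaperone median was 0.29. HSPA8, a constitutive chaperone, stood at 0.17 (adjusted p = 0.479).

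Of the 44 unfolded protein response genes 13 rose and 3 fell in VCaP, 21 and 3 when adjusted over the list alone, at a median of 0.29 (adjusted p = 0.000113, and adjusted p = 0.0808 with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, changed by 1.05 (adjusted p = 0.00192). Without arrays 1 and 2 it was 0.76 (adjusted p = 0.0991), and the list's median was 0.22 with 2 called (adjusted p = 0.000468). Of the 36 NRF2 targets 6 rose and 1 fell, 9 and 3 when adjusted over the list alone, at a median of 0.22 (adjusted p = 0.00349, and adjusted p = 0.117 with an estimated correlation). ME1, the cytosolic malic enzyme, rose by 0.91, and was 0.93 without both arrays, where the list's median was 0.01 with adjusted p = 0.404. Of the 33 histone genes 8 rose and 0 fell, 9 and 2 when adjusted over the list alone, at a median of 0.24 (adjusted p = 6.29e-05, and adjusted p = 0.142 with an estimated correlation), and without both arrays the median was 0.14 with 5 called (adjusted p = 0.0255). H2BC12 rose by 0.93 and H4C5 by 2.46 (0.77 and 1.34 without both arrays), and their probes are uncertain because histone genes are near-identical.

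The largest single VCaP changes included genes in and outside the lists. RETNLB, which encodes a secreted resistin-like protein, rose by 2.96 (SE 0.23, adjusted p = 4.62e-05), and S100P, a calcium-binding protein, rose by 2.47 (SE 0.23, adjusted p = 0.000139). AMACR, a racemase of branched fatty acids, rose by 2.19, and CAMK2N1, an inhibitor of CaM kinase II, by 2.02. Without arrays 1 and 2 these were 2.83, 2.35, 1.70 and 2.31. CTSD, which encodes cathepsin D, and CDC34, a ubiquitin-conjugating enzyme, changed by 2.26 (SE 0.67, adjusted p = 0.0458) and 2.15 (SE 0.58, adjusted p = 0.0304), and stood at 0.38 (adjusted p = 0.891) and 0.32 (adjusted p = 0.840) without arrays 1 and 2. Without VCaP GLIPR1 array 1 or 2, CTSD stood at 1.82 and 1.76 (adjusted p = 0.192 and 0.199) and CDC34 at 1.75 and 1.64 (adjusted p = 0.142 and 0.144). Without VCaP lacZ array 1, 2 or 3, CTSD stood at 2.26, 2.33 and 2.19 (adjusted p = 0.120, 0.113 and 0.142) and CDC34 at 2.19, 2.16 and 2.11 (adjusted p = 0.0846, 0.0916 and 0.105). ALDH5A1, succinic semialdehyde dehydrogenase, fell by 2.29 (SE 0.27, adjusted p = 0.000376), and MXI1, an antagonist of MYC, fell by 1.95. CD44, a cell surface receptor for hyaluronan, fell by 1.76. Without arrays 1 and 2 the values of these 3 genes were -1.68, -1.30 and -1.10. NUPR1, a stress-induced chromatin protein, changed by 1.90 (adjusted p = 0.00672) and by 0.76 without both arrays (adjusted p = 0.238).

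The other VCaP lists did not pass. Of the 12 GLIPR1 study genes 6 fell and 2 rose, 6 and 3 when adjusted over the list alone, at a median of -0.28 (adjusted p = 0.686). Of the 37 androgen response genes 5 rose and 4 fell (median -0.08, adjusted p = 0.876), and of the 12 luminal markers 1 rose and 3 fell (-0.25, adjusted p = 0.409). Of the 32 p53 targets 2 rose and 3 fell (0.0039, adjusted p = 0.898), and of the 47 interferon response genes 2 rose and 2 fell (-0.04, adjusted p = 0.854). Of the 11 fibroblast markers 1 rose, LUM by 1.26 (median -0.02, adjusted p = 0.823), of the 9 leukocyte markers 0 changed (-0.07, adjusted p = 0.876), and of the 8 embryonic kidney markers 1 rose and 1 fell (0.01, adjusted p = 0.823). Of the 32 NF-kB genes 4 rose and 4 fell (0.13, adjusted p = 0.144), of the 40 immediate early genes 6 rose and 8 fell (0.03, adjusted p = 0.876), of the 33 apoptosis regulators 3 rose and 4 fell (0.05, adjusted p = 0.876), and of the 33 TGF-beta, SMAD and matrix genes 1 rose and 4 fell (-0.07, adjusted p = 0.876). Of the 49 DNA replication genes 4 rose and 4 fell (-0.07, adjusted p = 0.982), and of the 37 glycolysis and hypoxia genes 4 rose and 4 fell (-0.08, adjusted p = 0.880). For androgen response, interferon response, DNA replication, glycolysis and fibroblast markers the test pointed up and the median was negative. Without arrays 1 and 2 none of these passed. Of the 49 oxidative phosphorylation genes 4 rose and 2 fell, at a median of 0.11 (adjusted p = 0.0865), and at 0.17 without VCaP GLIPR1 array 3 (adjusted p = 0.0179). Of the 58 ribosomal protein genes 0 rose and 1 fell, at a median of 0.02 (adjusted p = 0.823), and at -0.15 without arrays 1 and 2 (adjusted p = 0.00739), which turned the direction.

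**Figure D4:**
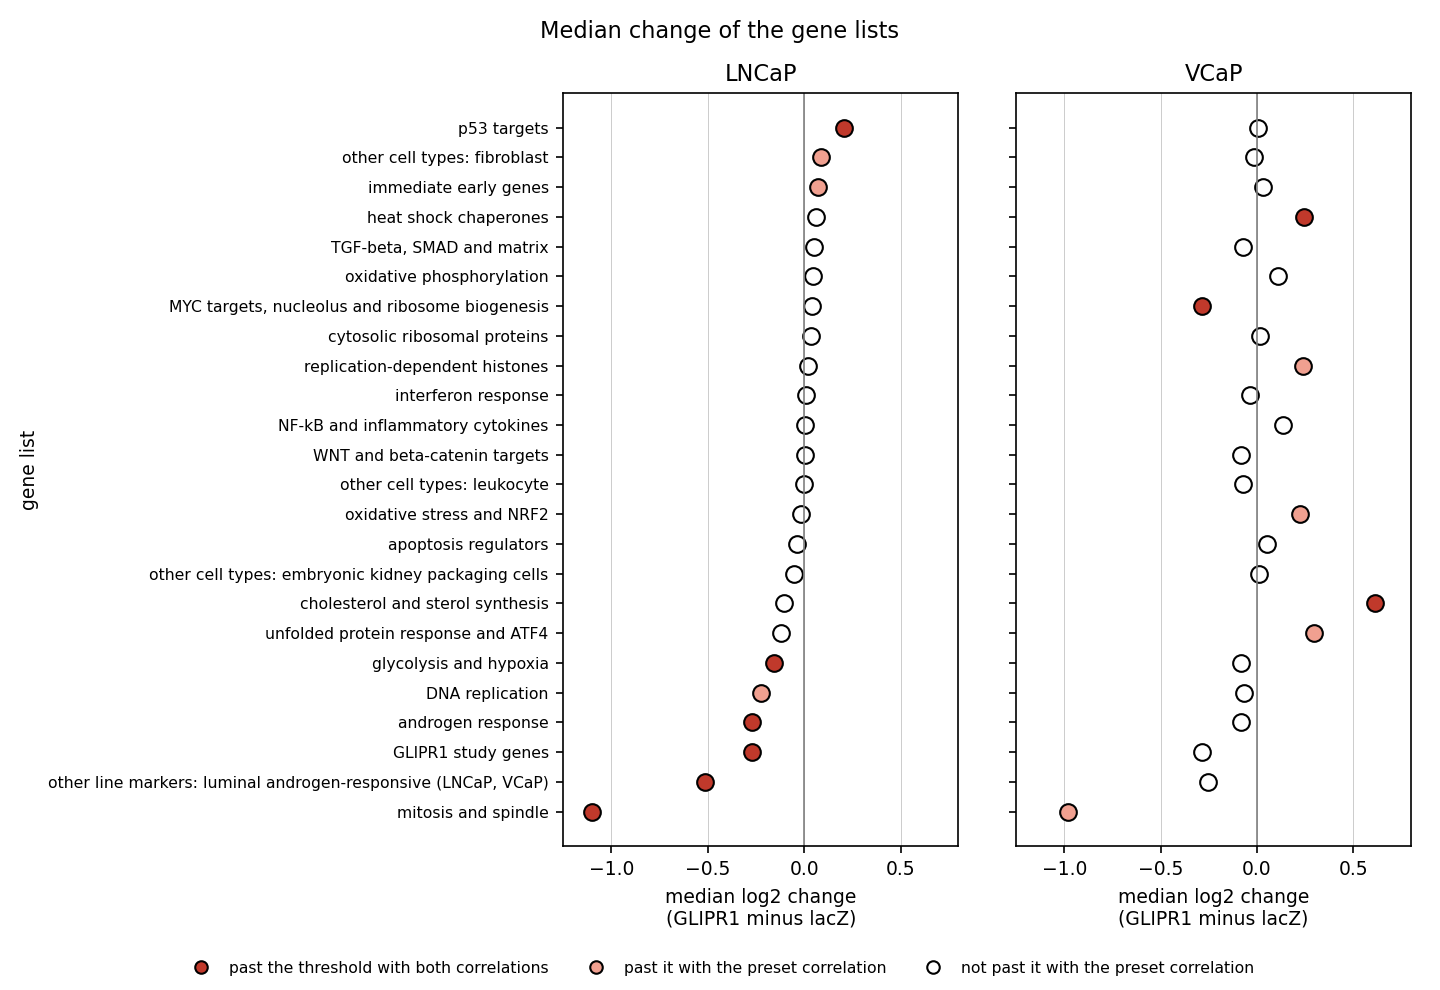
Median log2 change (GLIPR1 minus lacZ) of each of the gene lists in LNCaP and in VCaP, with fill for lists past the threshold of camera with the preset and with the estimated correlation. The mitosis and spindle list lies lowest in both lines, at -1.10 and -0.98, and cholesterol synthesis lies highest in VCaP at 0.61.

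In all, 3722 of 30557 probes passed in VCaP, 1578 higher and 2144 lower, 806 of them by at least 2-fold. Without GLIPR1 arrays 1 and 2 the count was 571, with 302 higher and 269 lower. It was 1489, 1485 and 9002 without VCaP GLIPR1 array 1, 2 or 3, and 1842, 1697 and 1572 without lacZ array 1, 2 or 3. Fitted on the 6 VCaP arrays alone, 1934 probes passed, and far fewer when single arrays were also left out, as given below. The fit over both lines shares 1 spread per probe among 4 groups, and the VCaP GLIPR1 group was the widest. Its array 3 lay at median absolute differences of 0.255 and 0.252 from arrays 1 and 2, against 0.125 to 0.135 within VCaP lacZ. The VCaP p-values of that fit may therefore be too small and its counts too high.

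For the mean effect over LNCaP and VCaP, mitosis and spindle genes were lower. Of the 50 mitosis and spindle genes 47 fell and 0 rose, 49 when adjusted over the list alone, at a median of -1.12 (adjusted p = 1.15e-44, and adjusted p = 0.0358 with an estimated correlation). CDC20 changed by -1.59 (SE 0.16, adjusted p = 0.000148), CENPE, the kinetochore kinesin, by -1.42 (SE 0.15, adjusted p = 0.000208), and CENPA, the centromeric histone, by -1.40 (SE 0.13, adjusted p = 0.000102). PTTG3P and FAM72D changed by -1.48 and -1.43, and are uncertain because near-identical copies exist. LUM rose by 1.77 (SE 0.11, adjusted p = 8.07e-06), FHL2 by 1.49, SERPINE2, a secreted protease inhibitor, by 1.09, and DUSP5 by 1.04. In VCaP without arrays 1 and 2, LUM, FHL2, SERPINE2 and DUSP5 stood at 1.10, 1.30, 1.48 and 0.77, and CENPE and CENPA at -1.0 and -1.06; CDC20 stood at -1.247 (adjusted p = 0.0651) against -1.56 with all arrays.

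Heat shock chaperones and cholesterol synthesis also passed for the mean effect with both correlations, and of the 2 lines each passed in VCaP only. In LNCaP cholesterol synthesis pointed the other way (-0.11, adjusted p = 0.152), and chaperones stood at 0.06 (adjusted p = 0.349). Of 31 chaperones 7 rose and 2 fell, 11 and 3 when adjusted over the list alone (median 0.23, adjusted p = 0.00242, and adjusted p = 0.0358 with an estimated correlation). Of 30 cholesterol genes 4 rose and 1 fell, 6 and 1 when adjusted over the list alone (median 0.22, adjusted p = 0.00261, and adjusted p = 0.0358 with an estimated correlation). Another 8 lists passed with the preset correlation and not with the estimated one. The last p of each group is the adjusted p with an estimated correlation. These were histones (0.19, 7 of 33 rose, adjusted p = 0.000141 and 0.134), luminal markers (-0.39, 4 of 12 fell, adjusted p = 0.00194 and 0.0723), MYC targets (-0.14, 7 of 45 fell, adjusted p = 0.0346 and 0.0723) and NRF2 targets (0.18, 3 of 36 rose and 1 fell, adjusted p = 0.0346 and 0.148). The others were the GLIPR1 study genes (-0.33, 5 of 12 fell and 1 rose, adjusted p = 0.0421 and 0.123), the unfolded protein response (0.13, 6 of 44 rose and 4 fell, adjusted p = 0.0471 and 0.219), oxidative phosphorylation (0.13, 1 of 49 rose, adjusted p = 0.0471 and 0.443) and DNA replication (-0.08, 7 of 49 fell, adjusted p = 0.0482 and 0.404). With the replicate block the GLIPR1 study genes did not pass for the mean effect (adjusted p = 0.111). Without VCaP GLIPR1 arrays 1 and 2, the mean effect gave -0.91 for mitosis, 0.11 for chaperones and 0.19 for cholesterol synthesis, each past the threshold. NRF2 targets (0.02, adjusted p = 0.525), the unfolded protein response (0.05, adjusted p = 0.164) and oxidative phosphorylation (0.0082, adjusted p = 0.697) did not pass then. The p53 targets (0.18, adjusted p = 0.00623), androgen response (-0.08, adjusted p = 0.0312) and fibroblast markers (0.06, adjusted p = 0.0393), which did not pass with all arrays, did so then. In all, 2453 probes passed, 1000 higher and 1453 lower. The count was 1595, 1609 and 7263 without VCaP GLIPR1 array 1, 2 or 3, 1621 and 1530 without VCaP lacZ array 2 or 3, 1295 without VCaP GLIPR1 arrays 1 and 2, and 4340 with the replicate block.

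Genes called in the same direction in both lines were more frequent than for independent lists. With 1 probe per gene, 124 genes were higher in LNCaP and 990 in VCaP, and 36 were shared against 8.12 expected (two-sided Fisher's exact test, p = 1.09e-14). Lower genes numbered 139 and 1561, and 86 were shared against 14.4 expected (Fisher's exact test, p = 7.90e-50). Genes called in opposite directions numbered 13. The 2 differences use no arrays in common, but both were tested with 1 shared estimate of the spread per probe. Calls in the 2 lines are therefore not independent, and the expected counts and p-values do not allow for this. Under the 75th percentile shift 17 higher and 73 lower genes were shared. The shared total of 122 was 76, 56 and 76 without LNCaP GLIPR1 array 1, 2 or 3, 72 without LNCaP lacZ array 2 or 3, 306 without VCaP GLIPR1 array 3, 75 without VCaP GLIPR1 arrays 1 and 2, and 227 with the replicate block. Across 15111 genes, which are not independent replicates, the changes in LNCaP and VCaP correlated with Pearson's r of 0.249 and Spearman's rho of 0.200. Pearson's r was 0.0856 without LNCaP GLIPR1 array 1, 0.400 without lacZ array 1 and 0.0985 without lacZ array 2.

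The difference between the lines was tested directly. The cholesterol synthesis list moved higher in VCaP than in LNCaP by a median of 0.59, with 3 of 30 members higher and 0 lower, 10 and 0 when adjusted over the list alone (adjusted p = 4.06e-08, and adjusted p = 0.00326 with an estimated correlation). MYC targets moved lower in VCaP, by a median of -0.30, with 1 of 45 called, 8 lower and 1 higher when adjusted over the list alone (adjusted p = 0.00309, and adjusted p = 0.0283 with an estimated correlation). The change of androgen response genes was less negative in VCaP than in LNCaP (medians -0.08 and -0.27), by a median difference of 0.23. Of 37 members 2 were called for this difference (camera adjusted p = 0.000706, and adjusted p = 0.0247 with an estimated correlation). LEF1 fell by 1.52 in VCaP and stood at 0.18 in LNCaP, a difference of -1.70 (SE 0.17, adjusted p = 0.00125). Its lacZ level was 6.83 in LNCaP and 12.42 in VCaP, which left less room for a fall in LNCaP. ME1 rose by 0.91 in VCaP and fell by 0.52 in LNCaP, a difference of 1.43 (SE 0.15, adjusted p = 0.00125). CBLN2 rose by 2.0 in LNCaP and stood at 0.30 in VCaP, a difference of -1.69 (SE 0.16, adjusted p = 0.000802). ANGPT2, an angiopoietin of vessel growth, rose by 1.77 in VCaP and stood at -0.59 in LNCaP, a difference of 2.36 (SE 0.21, adjusted p = 0.000802).

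Of 30557 probes 462 passed for the difference, 163 higher and 299 lower. Without LNCaP GLIPR1 array 2 or 3 the count was 149 and 137, and without LNCaP lacZ array 1, 2 or 3 it was 229, 222 and 159. Without VCaP GLIPR1 array 1, 2 or 3 it was 138, 155 and 5932, without VCaP lacZ array 1, 2 or 3 it was 137, 133 and 128, and without VCaP GLIPR1 arrays 1 and 2 it was 126. Under the 75th percentile shift it was 301, and with the replicate block 1514. The changes of the unfolded protein response and heat shock chaperones were also higher in VCaP than in LNCaP. Their median differences were 0.31 (2 of 44 called, camera adjusted p = 2.95e-06) and 0.34 (2 of 31 called, camera adjusted p = 0.00589). With an estimated correlation these lists gave adjusted p = 0.0331 and adjusted p = 0.0379. Without VCaP GLIPR1 array 3, MYC targets (-0.39, adjusted p = 0.0526) and heat shock chaperones (0.25, adjusted p = 0.0718) did not pass. Without VCaP GLIPR1 arrays 1 and 2, the medians of cholesterol synthesis, MYC targets, androgen response, the unfolded protein response and chaperones were 0.54, -0.34, 0.22, 0.31 and 0.25, each past the threshold.

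The lacZ arrays of both lines were compared to give the background between the lines. Of 30557 probes 11313 differed, 5546 higher and 5767 lower in VCaP, and 5240 by at least 2-fold. Mitosis and spindle genes lay higher in VCaP lacZ arrays by a median of 1.27, with 40 of 50 higher and 1 lower (adjusted p = 3.15e-10, and adjusted p = 0.182 with an estimated correlation), and immediate early genes by 0.63, with 23 of 40 higher and 1 lower (adjusted p = 4.05e-07, and adjusted p = 0.0617 with an estimated correlation). Histones lay lower by -0.55, with 19 of 33 lower and 1 higher (adjusted p = 4.21e-05, and adjusted p = 0.142 with an estimated correlation), and cholesterol synthesis by -0.38, with 15 of 30 lower and 4 higher (adjusted p = 0.0158, and adjusted p = 0.102 with an estimated correlation). Others past the threshold with the preset correlation alone were oxidative phosphorylation (-0.455, 25 of 49 lower and 5 higher, adjusted p = 0.00220), TGF-beta, SMAD and matrix (0.26, 16 of 33 higher and 5 lower, adjusted p = 0.00939) and DNA replication (0.47, 24 of 49 higher and 4 lower, adjusted p = 0.0158). MYC targets (-0.43, 21 of 45 lower and 8 higher) and the unfolded protein response (-0.57, 22 of 44 lower and 9 higher) both gave adjusted p = 0.0328. In the same order these 5 lists gave adjusted p = 0.281, 0.0996, 0.304, 0.111 and 0.238 with an estimated correlation.

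In DU145, 39 of 24745 tested entries passed between the GLIPR1 and lacZ arrays in limma, 18 higher and 21 lower, with changes between -1.72 and 1.24, and 2496 had an unadjusted p under the threshold. Without DU145 GLIPR1 array 1, 2 or 3 the count was 6, 4 and 444. It was 0 without lacZ array 1, 2 or 3, where 1740, 1841 and 1765 entries had an unadjusted p under the threshold. No gene was named, because the values did not follow the identifiers beside them.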

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

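The test against LNCaP replicate 1, the 3 tests of the DU145 values and the comparison with splits that part the LNCaP pairs for the mean effect and the difference were chosen only after the results were seen, and the other tests here were set before their results.

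Of the tested probes, 462 had a GLIPR1 effect that differed between VCaP and LNCaP by a test of the difference itself. Among single genes the VCaP change minus the LNCaP change was 2.01 for ZNF473CR, 2.36 for ANGPT2, 1.43 for ME1, 1.69 for GPNMB, 1.53 for BHLHE40 and 1.58 for CLC. It was -1.69 for CBLN2, -1.67 for LINC03018, -1.70 for LEF1 and -1.73 for RORB. LINC03018, LEF1 and RORB had lacZ levels of 6.16, 6.83 and 5.92 in LNCaP against 11.22, 12.42 and 10.25 in VCaP, which left less room for a fall in LNCaP. All 10 calls held without any single array and without VCaP GLIPR1 arrays 1 and 2. These genes were picked for the largest statistics in the same data, so this says little about the other calls. Without VCaP lacZ array 3 the count of probes passing fell to 128.

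Among gene lists the median difference was 0.59 for cholesterol synthesis, 0.36 for NRF2 targets, 0.34 for heat shock chaperones, 0.31 for the unfolded protein response, 0.27 for DNA replication, 0.25 for histones, 0.24 for luminal markers, 0.23 for androgen response and 0.20 for mitosis and spindle. It was -0.30 for MYC targets. Of these, NRF2 targets, DNA replication, histones, luminal markers and mitosis did not pass with the estimated correlation (adjusted p = 0.109, 0.274, 0.224, 0.109 and 0.350). Without VCaP GLIPR1 array 3 the call was lost for mitosis (0.02, adjusted p = 0.125), DNA replication (0.19, adjusted p = 0.0718), heat shock chaperones (0.25, adjusted p = 0.0718) and MYC targets (-0.39, adjusted p = 0.0526). DNA replication was also lost without LNCaP GLIPR1 array 1 (0.16, adjusted p = 0.0504) or lacZ array 2 (0.18, adjusted p = 0.110). Without VCaP GLIPR1 arrays 1 and 2, which leaves 1 array in that group, the mitosis difference was 0.50. The call was lost then for NRF2 targets (0.08), histones (0.04) and luminal markers (0.18).

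VCaP GLIPR1 arrays 1 and 2 stood apart from array 3. Across probes this gap followed the gap between LNCaP replicate 1 and replicates 2 and 3 with r = 0.559. The largest size for a VCaP lacZ array was 0.114, so a processing difference shared by these arrays may account for part of the gap. On that LNCaP contrast VCaP GLIPR1 arrays 1, 2 and 3 scored 0.511, 0.508 and -0.472, and VCaP lacZ arrays -0.436 to -0.521. Such a difference would therefore also enter the VCaP changes, the mean effect and the difference between lines. In arrays 1 and 2 it cannot be told apart from the virus. LNCaP RNA in the 2 arrays was excluded, because 16 genes bright in LNCaP and dim in VCaP had a median rise of 0.021. A stronger response to GLIPR1 stayed open: over 453 genes called in LNCaP with the replicate block the median signed gap was 0.067, between the limits set for and against it. Over these genes the median signed change was 0.382 in arrays 1 and 2 and 0.374 in array 3. In arrays 1 and 2, 56.5% of the genes lay further in the LNCaP direction. The share of each cause is not known.

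The DU145 values did not follow their probe identifiers. Ribosomal protein probes, at a median percentile of 99.4 in LNCaP and 99.3 in VCaP, stood at 32.2 in DU145, which excluded a different expression programme as the cause. At 1 common offset the highest median rank correlation was 0.111, under the limit of 0.3, and 0.0345 in shuffled windows. Both searches covered only offsets within 100 rows, in the first 12000 rows. With an offset allowed to vary along this stretch the median was 0.482 over 29 windows, against 0.144 at distant positions. The best offsets ran from -93 to -50. In this stretch the spread of best offsets excluded 1 constant offset as the whole cause and left open values out of step by a varying offset. Restoring the order was not tried.

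Mitosis and spindle genes were lower in the LNCaP arrays labelled GLIPR1. The fall of the list median was at least -1.09 in size in all 3 replicate pairs and at most -1.31, so no single pair carried it. A difference between replicates shared by both viruses cancels from this comparison, so the test could not have shown it as a cause. The lowest of 10000 random lists matched on level had a median of -0.17 against -1.10 for the list, which excluded a shift of bright probes. Neither test separates an effect of GLIPR1 from another property of that virus preparation.

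Labels were also permuted, between viruses within each line and, for the lacZ arrays, between lines. In LNCaP, VCaP, DU145 and between the lacZ arrays, 1 of 10 splits, the real one, gave as many calls as observed, and 10 splits are too few for a share under 0.05. For the mean effect 1 of 100 splits did so (2453 calls against at most 664), although at an unadjusted threshold the highest other split had 6820 probes against 6753. Those splits include some that break the LNCaP pairs. Among the 38 that part all LNCaP pairs the real one alone gave as many, against at most 328. At the unadjusted threshold the real one had 6753 against at most 5120. No other of these splits thus matched the real one, but the 38 were chosen after the results were seen. Replicates may be technical, so regrouping the arrays cannot exclude chance between cultures. For the difference between lines 4 of 100 splits gave as many calls as observed (462 calls against 2967, 2374 and 664). That share is under 0.05, but the 3 larger splits kept the real VCaP groups and put both LNCaP replicate 1 arrays on one side, so the count of 462 was not the largest that the structure of these samples could give. Among the 38 that part all LNCaP pairs the highest other count was 367, and at the unadjusted threshold 5089 against 5011.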

How the results depend on the processing

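Leaving out VCaP GLIPR1 arrays 1 and 2, the 75th percentile filter, the LNCaP replicate 1 score, the fits of 1 line with the block and the fits of VCaP alone without single arrays were chosen only after the results were seen. So was the use of several other settings on the GLIPR1 probe, the shared genes, their correlation, the lists and the named genes. Where no reason is given below, the cause was not tested.

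Leaving out 1 array at a time, calls ranged from 182 to 947 in LNCaP, 1485 to 9002 in VCaP, 0 to 444 in DU145, 1530 to 7263 for the mean effect, 128 to 5932 for the difference and 9681 to 12861 between lacZ arrays. Genes shared between lines ranged from 56 to 306, Pearson's r between their changes from 0.0856 to 0.400, and called lists for the difference from 7 to 15. With VCaP fitted alone (1934 calls), the counts were 154, 81 and 11829 without GLIPR1 array 1, 2 or 3 and 2, 2 and 1 without lacZ array 1, 2 or 3. Without VCaP GLIPR1 arrays 1 and 2 together, calls were 721 in LNCaP, 571 in VCaP, 1295 for the mean effect and 126 for the difference, 75 genes were shared, and the GLIPR1 probe in VCaP stood at -0.56 (adjusted p = 0.166). That fit leaves 1 VCaP GLIPR1 array, which is assumed to vary like the other groups.

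At an adjusted p under 0.01, calls were 170 in LNCaP, 1330 in VCaP, 4 in DU145, 998 for the mean effect and 71 for the difference, with 46 genes shared. With arrayWeights they were 1025, 11429, 228, 8690 and 7447, with 360 shared. With the LNCaP replicate 1 score as covariate they were 1269 in LNCaP and 958 for the difference, with 281 shared. Under the 75th percentile shift the difference had 301. Called lists with the estimated correlation numbered 3 in VCaP, 3 for the mean effect and 5 for the difference. For the mean effect 5 lists passed with the 75th percentile filter and 7 with the stricter filter, and fry called 13 in VCaP.

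With the replicate block, calls were 671 in LNCaP, 6282 in VCaP, 14 in DU145, 4340 for the mean effect and 1514 for the difference, with 227 genes shared. In fits of 1 line with the block they were 2010 in LNCaP and 1868 in VCaP, where the GLIPR1 probe stood at -0.74 (adjusted p = 0.0545). In LNCaP the block brought TP53I3, TIGAR and CDC45 past the threshold and changed no other call of a gene or list reported for that line; genes of the lists that are not reported for LNCaP also gained calls. In VCaP it brought oxidative phosphorylation (adjusted p = 0.0367) and CTNNB1 (adjusted p = 0.00152) past the threshold. For the mean effect it ended the call of the GLIPR1 study genes (adjusted p = 0.111) and brought androgen response past the threshold (adjusted p = 0.0474), and for the difference it brought the GLIPR1 study genes (adjusted p = 0.0207) and p53 targets (adjusted p = 0.0489) past it. Same-numbered samples correlated at 0.18, 0.04 and 0.21 in VCaP, against -0.19 to 0.16 for different numbers. The VCaP GLIPR1 deviations carry the gap between arrays 1 and 2 and array 3, so this comparison cannot decide on pairing in VCaP. In DU145 the values were -0.01, 0.02 and -0.03, against -0.05 to 0.05 for different numbers, and no pairing was seen. No paired analysis was possible for the lacZ arrays because the 2 lines lie in different blocks.

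Results whose direction turned were not past the threshold in the comparison itself. The direction of a list is that of its test, so a median can keep its sign. The 75th percentile shift turned CTNNB1 in LNCaP (-0.014), DNA replication in VCaP (-0.17), MYC targets (0.028) and NRF2 targets (-0.037) in LNCaP, and the difference for ribosomal proteins (-0.28) and interferon response (-0.052). The 75th percentile filter turned immediate early genes in VCaP (-0.13). Ribosomal proteins turned for the difference with the second deposited table (-0.011), no background correction (-0.0081), no filter (-0.026) and the stricter filter (-0.0083). No filter also turned DNA replication in VCaP (-0.064) and embryonic kidney (-0.011) and leukocyte markers (-0.0065) in LNCaP. The mean over probes turned NF-kB in LNCaP (-0.036) and TGF-beta in VCaP (0.043). In VCaP fry turned DNA replication (-0.067), androgen response (-0.082), apoptosis regulators (0.055), glycolysis (-0.082), immediate early genes (0.029) and p53 targets (0.0039), and for the difference apoptosis regulators (-0.084) and ribosomal proteins (-0.0081).

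The fits of 1 line, with or without the block, turned DNA replication in VCaP (-0.067) and apoptosis regulators in LNCaP (-0.037). The block turned DNA replication in VCaP (-0.067) and, also in the fit of 1 line, NRF2 targets in LNCaP (-0.018). The score turned CTNNB1 in LNCaP (-0.0058), androgen response (-0.025), ribosomal proteins (-0.029), immediate early genes (-0.017) and leukocyte markers (0.045) in VCaP, and the difference for ribosomal proteins (-0.088) and interferon response (0.088). Without both VCaP arrays, apoptosis regulators turned in LNCaP (-0.037), VCaP (-0.068) and the difference (-0.039), glycolysis (0.028), immediate early genes (0.0087) and oxidative phosphorylation (-0.040) in VCaP, and interferon response (0.011) and oxidative phosphorylation (-0.072) for the difference. Ribosomal proteins turned and passed then, in VCaP (-0.15, adjusted p = 0.00739) and for the difference (-0.18, adjusted p = 0.000694).

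Leaving out 1 array turned further results, with these ranges. In LNCaP they were -0.37 to 0.45 for CTNNB1, 0.018 to 0.066 for MYC targets, -0.030 to 0.15 for oxidative phosphorylation, -0.037 to 0.043 for apoptosis regulators, -0.089 to -0.023 for embryonic kidney markers, -0.077 to -0.014 for the list oxidative stress and NRF2, LNCaP, and -0.022 to 0.072 for ribosomal proteins. In VCaP they were -0.12 to -0.023 for DNA replication, -0.027 to 0.10 for ribosomal proteins, -0.055 to 0.015 for p53 targets, -0.022 to 0.080 for immediate early genes and -0.094 to 0.024 for interferon response. For the difference they were -0.15 to 0.040 for interferon response and -0.065 to 0.091 for ribosomal proteins.

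Of 144 tests of single genes, 21 lost and 3 gained a call without both VCaP arrays, 8 and 1 in fits of 1 line, and 4 lost it under the 75th percentile shift. These 144 tests cover genes kept for the text, from which most genes with calls lost without single arrays had been left out. The share of changed calls may therefore be too low for all genes that the rule selected. Of 75 tests of lists in LNCaP, VCaP and the difference, 13 lost the call with the estimated correlation, beside which called lists went from 11 to 3 for the mean effect and from 10 to 0 between lacZ arrays, and 15 gained and 3 lost it with fry. For DU145 the background, shift and second table alternatives were not run, because its deposited values were already normalized and equal in both tables. A chip block was not run, because the sources used here name no chip. Signal over background limits dim probes, for which a change is compressed by the offset, and a 1.5-fold change was recovered for 20.9% of simulated probes in LNCaP.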
